A study of Microtus ochrogaster with 2 samples.

How the data were processed

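Chromatin from the retrosplenial cortex of male prairie voles aged 30 to 40 days gave 1 H3K4me1 ChIP library and 1 input library, per the labels. The series names 8 males, and how many of them went into each library, or whether their chromatin was pooled, is not given in the sources used here. Both libraries entered 1 peak list as deposited by the authors, and they were the only 2 groups, with 1 sample each.

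Peaks were called with MACS 2.0.10.20131216 in paired-end mode, per the file headers, with a q cutoff of 0.05, an effective genome size of 1.89e+09, 1 duplicate fragment kept per position, broad calling off and a fragment size of 256 bp. The submitters' processing notes list BWA 0.7.12, SAMtools 0.1.19 and MACS2 2.0.10, while paths in the file header name a Stampy alignment, so the aligner of the deposited list is open. Per the file headers the ChIP library held 41470832 fragments before and 37430265 after the filter, and the input library 49780235 and 47554684. The larger library was scaled to the smaller one. The deposited signal of a peak is its pileup, the coverage by ChIP fragments at the summit. The authors' fold enrichment is the ratio of that pileup to the background that the caller set for the peak from the input. The deposited −log10 p and −log10 q values come from the caller's Poisson test and its correction for multiple tests. All of these are the authors' values for single peaks and were used only to describe, rank or filter peaks within the list.

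The local background of each peak was computed from pileup and fold, each with the caller's added pseudocount of 1. The Poisson p recomputed from it was within 0.05 of the deposited −log10 p at all 36238 peaks. The lowest background was 6.23 fragments, a floor shared by 12487 peaks (34.5%) on many sequences. For these peaks the fold is therefore not taken over a background of their own locus. At 729 peaks (2.01%) the background was over 5 times that value, and these had a median pileup of 135 and a median fold of 1.79. The limit of 5 times was chosen after the data were examined.

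The genome build of the peak list is not given in the sources used here, and no genome sequence was used. Gene positions came from a table of assembly MicOch1.0, with 20077 protein-coding genes and no strand or exons. The match of builds was settled from the data: sequence names were shared, and 2472 peaks lay 1 to 2.5 kb from a gene end, against 1190 to 1371 after all peaks were shifted by 10 to 200 kb. Sequence by sequence, with shifts of 20 to 200 kb, the unshifted count was the highest on 26 of 28, the exceptions being LG12 and the X. The same window was later used as a distance class, so that class is not independent of the match. Of the peaks, 27022 (74.6%) and of the genes 13975 (69.6%) lay on the parts of those 28 sequences that were used. Genes and peaks on unplaced sequences, on chromosome 14 (in several pieces) and on chromosome 6 below 20 Mb were left out. Peak coordinates are given as deposited, counted from 1, and no coordinate of the gene table is given.

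Location was tested on peak midpoints against 1000 random placements within the same sequence, and a share was called apart when it lay outside the range of all placements. Coverage around gene ends was counted in 100 bp bins over 10 kb on each side, with 95% Wilson intervals, which cover counting error only. Medians of fold and width were compared with 10000 resamples of peaks. For each gene list, the median percent of the locus covered was placed among 10000 random lists, in which each member was replaced by 1 of the 200 genes nearest in locus length, with ties counted as a middle rank. A list was called beyond percentile 2.5 or 97.5. No p-value across genes was computed. Each list had 11 alternatives. The gene lists and the tests of lists, clusters and the X were fixed before the data were examined. The settings of 96 of the 194 alternatives were fixed before as well. Some of these 96 were settings for location, gene ends and peak strength, so they were run on tests whose form came after. The other 98 alternatives were added after, and so were the tests of location, gene ends and peak strength in the form used. The distance classes, the share of members with a peak, peaks per 10 kb of locus, X peaks per gene, the rotation, the runs without X genes or high-background peaks, and the weight given to the mean once many medians proved to be 0 came after. A rule that gives tied medians no direction was also set after the results were seen.

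On simulated lists of 20 genes, among 13975 genes, a 2-fold rise in peak density, simulated only in genes longer than 20 kb, was called in 8 of 10 lists by median and 6 of 10 by mean, and a 4-fold rise in 10 of 10 by both. Shorter genes, which include many of the listed ones, were not simulated with a rise. Of 200 random lists with no change, 12 were called by median and 16 by mean. All simulated peaks were placed uniformly along each sequence, apart from the added ones. Real peaks were not spread evenly (gene bodies held 1.66 times the share of random placements), so these rates need not hold for the lists here.

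The genes named follow a rule fixed beforehand. It took from each list the 3 members with the highest percent covered and the first 2 in alphabetical order without a peak. It added the 10 genes of highest coverage with loci of at least 20 kb, the nearest genes of the 5 peaks of highest fold, the genes in the 5 largest clusters, and Avpr1a and Oxtr. A few genes that the rule takes are not reported here. Other genes named were chosen after their values were seen. Promoter, exon and untranslated classes, profiles around start sites, matching on CpG content, 23 motifs and a list of olfactory and vomeronasal receptors were planned and not analysed here, since they need strand, exons, sequence or gene descriptions. Distances to gene ends took the place of those to start sites. Avpr1a and Oxtr were not analysed here, because neither had a usable position in the table.

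Alternatives kept the 50% of peaks with the higher q rank or the 25% with the highest fold, changed the flanks to 0 or 50 kb, used means, rotated all peaks of a sequence, and changed the joining distance of clusters from 12.5 to 5 kb. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.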

Results

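The data were 1 list of H3K4me1 peaks from the retrosplenial cortex, a dorsal midline area of the cerebral cortex, of male prairie voles (Microtus ochrogaster) aged 30 to 40 days. H3K4me1 is histone H3 carrying a single methyl group on lysine 4, a mark found at enhancers and beside active promoters. The list compared 1 ChIP library, made with an antibody against H3K4me1, with 1 input library of the same tissue. The series names 8 males, and how they were spread over the libraries is not given in the sources used here. After the peak caller's filter the ChIP library held 37430265 fragments and the input library 47554684. With 1 library of each kind there was no replicate check, so intervals and percentiles describe this peak list and not the spread between animals.

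The first question was where, and how strongly, the mark was enriched over the input. The list held 36238 peaks on 585 sequences, and none overlapped another. They covered 19.6 Mb, or 1.04% of the effective genome size given to the caller. The median peak was 433 bp wide (quartiles 327 and 627 bp) and held 22 ChIP fragments at its summit. Its fold enrichment over the caller's background from the input, the authors' own value per peak, was 2.84 (quartiles 2.59 and 3.18). Enrichment reached 4-fold at 1043 peaks (2.88%) and 5-fold at 51. The 18 named chromosomes carried 20888 peaks and the 10 linkage groups 6276. A further 1217 lay on unlocalised sequences, 7851 (21.7%) on unplaced ones and 6 on 1 further sequence. Where the background stood at its lowest, as at 34.5% of peaks, the weakest listed peak had 16 fragments and 2.35-fold enrichment. Over higher backgrounds enrichment down to 1.17-fold was listed.

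The second question was how the peaks lay relative to genes. It was asked of the 27022 peaks (74.6%) on 28 sequences that could be matched to gene positions in assembly MicOch1.0. Chromosome 6 below 20 Mb was left out, and only protein-coding genes placed on these sequences counted as genes. Gene bodies held 70.6% of the peak midpoints (95% Wilson interval 70.01 to 71.1%), against 42.4% (range 41.5 to 43.4%) in 1000 random placements on the same sequences, a ratio of 1.66. The bands 1 to 2.5 kb from a gene end held 9.15% (8.81 to 9.50%) against 4.24% (3.87 to 4.63%), a ratio of 2.16. Regions more than 25 kb from any placed protein-coding gene held 18.96% (18.5 to 19.4%) against 39.4% (38.4 to 40.3%), a ratio of 0.481. The 500 bp on either side of a gene end held 1.45% (1.32 to 1.60%), which lay within the range of the placements (1.44 to 1.92%). These distance classes were chosen after the data were examined, and random placements could fall in assembly gaps.

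Around 27950 ends of protein-coding genes, peak coverage was lowest at the end itself and rose on both sides. A peak covered 0.664% of ends at the end (Wilson interval 0.577 to 0.768%). Coverage was 3.70% (3.48 to 3.92%) at 1250 bp inside the gene, 5.57 times the value at the end, and 1.66% (1.51 to 1.81%) at 1250 bp outside it. In the last 1 kb of the window it was 1.19% on the inward side and 0.815% on the outward side. Inward bins did not stop at the other end of a gene, so in genes shorter than the distance they lay beyond that end. Start and stop of transcription were not told apart, because strand was not used here.

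**Figure D1:**
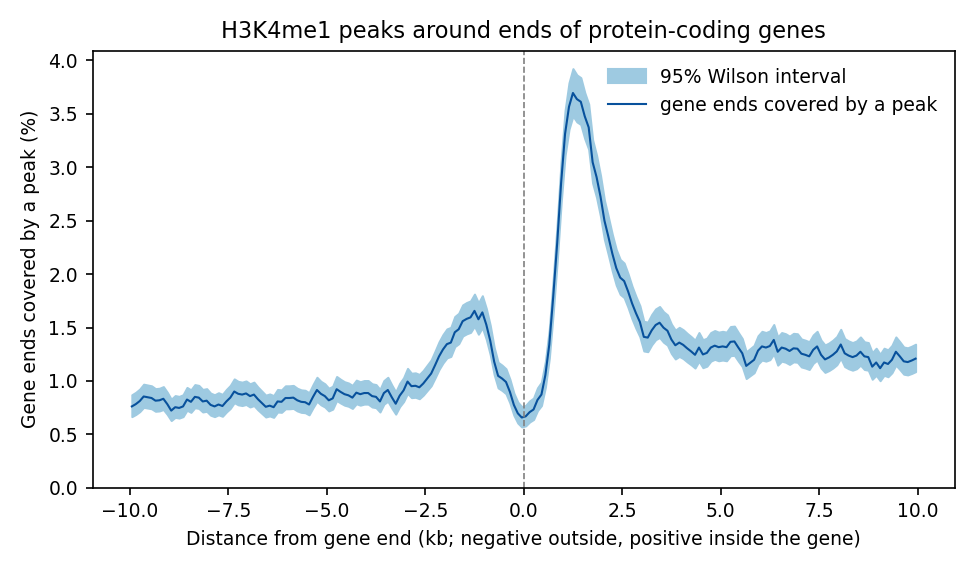
Percent of protein-coding gene ends covered by an H3K4me1 peak (vertical axis) by distance from the end in kb (horizontal axis, negative outside the gene and positive inside), with the 95% Wilson interval shaded. Coverage is lowest at the end (0.664%) and highest at 1250 bp inside the gene (3.70%). In genes shorter than the distance, positive positions lie beyond the other end of the gene.

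Peak strength differed little with distance from a gene end. The 1095 peaks within 1 kb of an end had a median enrichment of 2.77-fold, and the 19297 peaks beyond 10 kb had 2.85-fold. The difference of near minus far was -0.0793 (95% interval -0.0888 to -0.0260 over 10000 resamples of peaks). Median width was 403 bp near and 426 bp far, a difference of -23 bp (-33 to -13 bp). Both directions turned when peaks within 2.5 kb were set against those beyond 25 kb, with 0.0291 (0.00521 to 0.0570) in fold and 31 bp (21 to 41 bp) in width.

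The third question was which gene groups carried the mark in this cortical area. For 14 lists fixed before the data were examined, the percent of each gene locus (the gene with 5 kb on each side) covered by peaks was compared with 10000 random lists matched on locus length. Of all 13975 genes, 54.0% had no peak in the locus, and 9 of the 14 lists had a median coverage of 0. A list was called when it lay outside the central 95% of its random lists. Among 200 simulated lists with no change, 12 did so by median and 16 by mean. The simulated peaks were placed uniformly, unlike the real ones, so the rates here may differ.

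Activity-regulated genes, which neurons switch on with firing, stood at percentile 99.6 by their median coverage of 3.32%, and 13 of 15 carried a peak. Dusp1, a phosphatase that acts on MAP kinases, had 7.72% of its locus covered, and Arc, a postsynaptic protein, had 6.08%. The transcription factor gene Jun had 5.89%, while Egr1 and Klf4 had no peak. Dusp1, Arc and Jun had their peaks in the flanks and none with its midpoint inside the gene, and with gene bodies alone the list stood at percentile 48.9. It also lay within the random range by its mean (percentile 93.2), with 50 kb flanks (85.6) and with the 25% of peaks of highest fold (49.985). With gene bodies alone, and with the 25% of highest fold, the list's median and the median of its random lists were 0. Those percentiles reflect ties and do not tell whether the excess was lost.

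Synapse genes stood at percentile 99.15 by a median of 1.73%, and 18 of 20 carried a peak. Bsn, a scaffold protein of the presynaptic active zone, had 10 peaks over 4.84% of its locus. Dlg4, which encodes the postsynaptic scaffold PSD-95, had 3 peaks over 4.38%, and Nrxn2, a presynaptic adhesion molecule, had 6 over 3.51%. Lrrtm2 and Nlgn2 had none. By the mean, the synapse list stood at percentile 85.6, within the random range.

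Housekeeping genes stood at percentile 99.3 by a median of 2.66%, with a peak at 10 of 15. Rps18 and Rplp0, both ribosomal protein genes, had 7.44% and 5.25% of their loci covered, and Sdha, a subunit of succinate dehydrogenase, had 4.94%. Chmp2a and the X-linked Hprt1 had no peak. The list fell within the random range by its mean (90.2), by the share of members with a peak (96.3), with 50 kb flanks (95.1), and with the stronger 50% of peaks by q (47.3) or 25% by fold (49.9). In both runs on stronger peaks the list's median and the median of its random lists were 0. Those percentiles mostly reflect ties and do not tell whether the excess was lost.

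Excitatory cortical neuron genes lay within the random range by median (percentile 63.1) and by mean (91.4), although 14 of 17 carried a peak. Mef2c, a transcription factor of cortical neurons, had 32 peaks over 15.9% of its locus. Camk2a, a kinase abundant at excitatory synapses, had 7 peaks over 6.15%, and Nrgn, a calmodulin-binding postsynaptic protein, had 1 peak over 5.64%. Fezf2 and Neurod1 had none. The midpoint of the Nrgn peak lay in a flank, outside the gene.

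Inhibitory neuron genes carried a peak at 3 of 16 loci. These were Erbb4, a neuregulin receptor, with 26 peaks over 0.943% of its locus, Sox6 with 8 over 0.668% and Nxph1 with 2 over 0.286%. Calb2 and Dlx1 had none. The list stood at percentile 15.4 by its median, which was 0, and at 0.03 by its mean.

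Social neuropeptide and receptor genes, a group studied in prairie voles for pair bonding, carried a peak at 5 of 16 loci. Crhr2, a receptor for urocortins, had 1 peak over 0.769% of its locus, the progesterone receptor gene Pgr 1 over 0.628% and the mu opioid receptor gene Oprm1 1 over 0.573%. The vasopressin receptor gene Avpr1b had none. The list stood at percentile 10.9 by its median, which was 0, and at 0.03 by its mean. The vasopressin receptor Avpr1a and the oxytocin receptor Oxtr were not analysed here.

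Glial lists lay within the random range by median and by mean. Astrocyte genes carried a peak at 3 of 10 loci (percentile 25.3 by median, 56.4 by mean), led by Aldoc with 8.66% covered, the glutamate transporter Slc1a3 with 3.67% and the bicarbonate cotransporter Slc4a4 with 2.84%. Acsbg1 and the water channel Aqp4 had none. Oligodendrocyte lineage genes carried one at 8 of 14 (51.1 and 28.0), led by Cspg4 with 3.46%, Ugt8 with 2.97% and the myelin glycoprotein gene Mog with 2.85%, while Gpr17 and Mag had none. Microglia genes carried one at 5 of 15 (29.7 and 11.96), with Tmem119 at 3.598% and Irf8 at 1.90%, while the complement genes C1qa and C1qb had none. At Aldoc and Tmem119 all peaks had their midpoints in the flanks, outside the gene. With 50 kb flanks the astrocyte list lay below the range, at percentile 0.89.

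Endothelial and pericyte genes carried a peak at 2 of 12 loci (percentile 10.7 by median, 1.8 by mean). Pdgfrb, a growth factor receptor of pericytes, had 3.48% covered and Emcn 1.37%, while Cdh5 and Erg had none. Among tissues not sampled, hepatocyte genes carried a peak at 3 of 19 loci (41.7 and 0.39), with Hnf4a at 2.73%, Alb at 1.24%, Cps1 at 0.521% and none at Ahsg or Ambp. Epithelial genes carried one at 3 of 16 (21.1 and 0.25), with Lamb3 at 2.68%, Ppl at 1.35%, Tp63 at 0.125% and none at Cdh1 or Dsg3. Striated muscle genes carried one at 4 of 16 (35.6 and 11.8), with Acta1 at 5.35%, Mylpf at 4.14%, Cacna1s at 0.504% and none at Actn3 or Des. The peaks at Alb, Ppl, Acta1, Mylpf and Cacna1s had their midpoints in the flanks, outside the genes. Hox genes carried none at 18 of 18 loci (49.6 and 0.44), Hoxc10 and Hoxc11 among them, and as neighbours in clusters they are not independent. By median 3 lists lay above the range, none of them by mean, and by mean 6 lay below. The medians of those 6 were 0, and their random lists tied with them at 0 too often for the median to call them below.

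**Figure D2:**
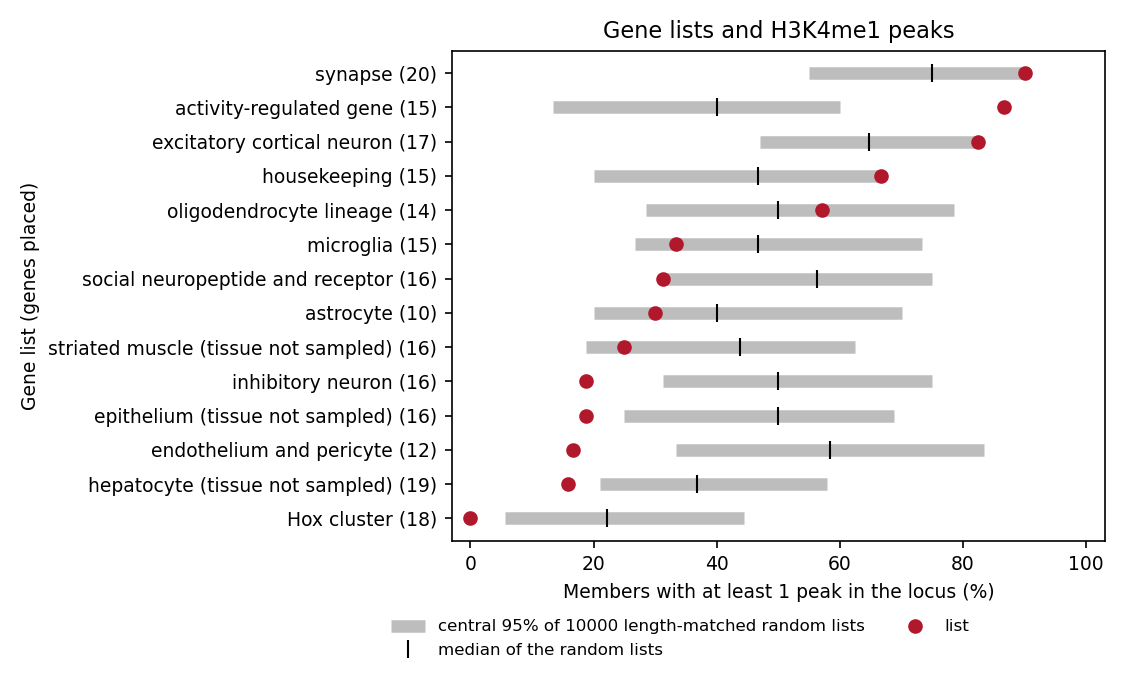
Percent of each list's genes with at least 1 H3K4me1 peak in the locus (red points), with the median (black line) and the central 95% (grey bar) of 10000 length-matched random lists; numbers in brackets are genes placed. By percentile, activity-regulated (86.7%) and synapse genes (90%) lie above the limits. Inhibitory neuron, social neuropeptide, endothelial and pericyte, hepatocyte, epithelial and Hox genes (0% to 31.25%) lie below them. The synapse and social neuropeptide shares equal the end of their grey bar, so these calls rest on the middle rank given to ties. Excitatory neuron (82.4%) and housekeeping genes (66.7%) equal their upper end too and are not called. This measure was chosen after the data were examined.

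Among genes with loci of at least 20 kb, Cxxc5, a zinc finger protein gene, had the highest coverage, with 14 peaks over 32.8% of its locus. The neighbouring genes Clptm1l and Tert, the telomerase catalytic subunit, followed with 30.0% and 26.3%. Their strongest peaks had 77 and 66 fragments but only 2.23-fold and 2.41-fold enrichment, so the local background there was raised. The next were Dexi (24.3%), LOC101984150 (24.2%), the chromatin reader Zmynd8 (23.2%), Ahdc1 (22.5%), LOC101987217 (22.4%), the protocadherin Pcdh1 (22.1%) and Btd, which encodes biotinidase (21.9%).

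Nearby peaks joined into 20984 clusters, of which 67.9% were single peaks and 1000 held 5 or more. The cluster with the most bases under peaks lay over Tcf4, a basic helix-loop-helix transcription factor of neurons, on chromosome 18 (54671105 to 54859038), with 51 peaks covering 48590 bp. The next lay over LOC106143776, LOC101983858 and LOC101984150 on chromosome 5 (42833315 to 43014970), with 49 peaks covering 40941 bp. The cluster at rank 3 was on an unplaced sequence, with 25 peaks covering 26951 bp. Zmynd8 on linkage group 8 (12626912 to 12707316), at rank 5, had 21 peaks covering 25088 bp. With a shorter joining distance of 5 kb, the top cluster was the unplaced one, with 26951 bp, and 6 of the top 10 overlapped a top cluster of that setting.

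The 5 peaks of highest fold all lay on unplaced sequences, where no gene was assigned. Among placed peaks, and chosen after their values were seen, the highest was on chromosome 8 (40613906 to 40615784), outside genes and nearest to Frmd8, with 52 fragments and 6.56-fold enrichment. The next were inside gene bodies, in Ncoa1, a nuclear receptor coactivator (5.94-fold), the integrin gene Itga11 (5.85-fold), Pfkm, the muscle phosphofructokinase (5.81-fold), and Ralgps1 (5.76-fold).

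The last comparison set the X chromosome, of which males carry 1 copy, against the other sequences. The X carried 62 peaks, or 1.003 per Mb, and the 27 autosomal chromosomes and linkage groups carried a median of 16.5 per Mb (range 7.60 to 21.8). The ratio of the X to that median was 0.0609, and the X lay below each of the 27. Per protein-coding gene, the X carried 0.188 peaks and the autosomal sequences 0.933 to 3.31. Of the X peaks 29.0% (18 of 62) had a background over 5 times the lowest, against 0 to 2.38% on autosomal sequences. The denominators were spans from end to end, with gaps included, and chromosome 6 entered only beyond 20 Mb.

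**Figure D3:**
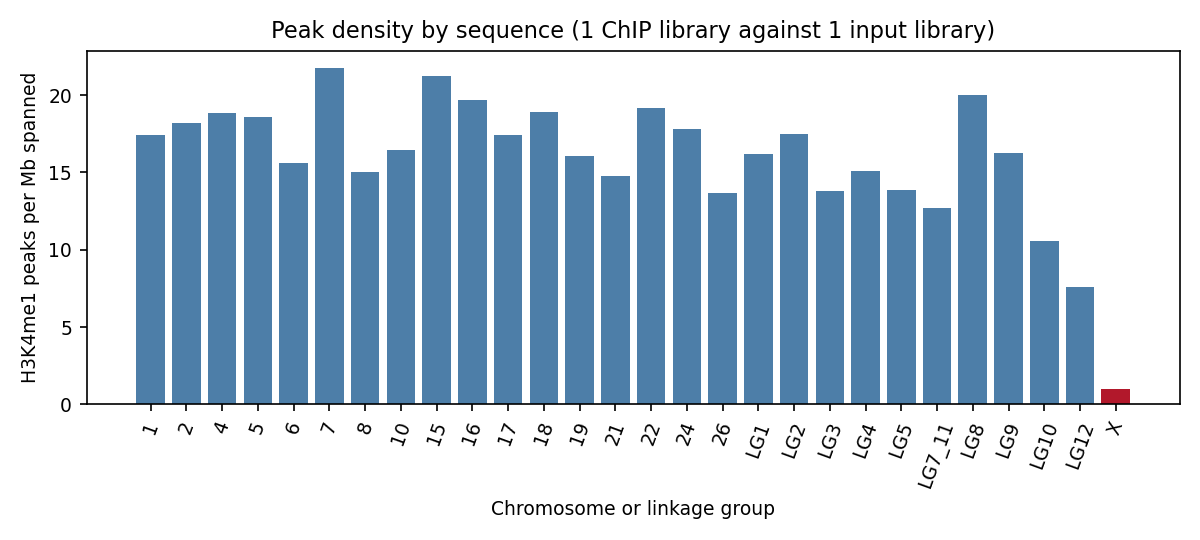
H3K4me1 peaks per Mb spanned (vertical axis) on each of 27 autosomal chromosomes and linkage groups (blue bars) and the X chromosome (red bar), from 1 ChIP library against 1 input library. The X stands at 1.003 per Mb and the autosomal sequences between 7.60 and 21.8 per Mb.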

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

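The comparisons in this part were chosen after the values were seen, and no technical or biological explanation was tested for them. Peaks on unplaced sequences numbered 7851, and they entered no comparison with genes although they lay above the input background by the caller's test. Of the 729 peaks with a background over 5 times the lowest, 64.1% were on unplaced sequences. The highest fold of the whole list, 26.9, was at an unplaced peak with 280 fragments. All 5 peaks above 10-fold were unplaced, with 11.3-fold to 26.9-fold enrichment and 81 to 280 fragments, and 4 of them started within 2.5 kb of the start of their sequence. The next highest fold in the list was 6.56. A single further sequence, outside the chromosomes, linkage groups and unplaced sequences, carried 6 peaks with 1.51-fold to 3.46-fold enrichment. One of them, at 93158 to 94385, had 690 fragments over a local background of 457 fragments.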

How the results depend on the processing

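The runs by share of members with a peak, by peaks per 10 kb of locus, by X peaks per gene, without X genes, without high-background peaks and with rotation, 98 of 194 in all, were chosen after the data were examined. Of the 194, 144 kept the direction and call, 29 took a result past its limits and 16 brought it back within them. A further 3 moved a value and 2 turned a direction. The cause was not tested except where a smaller peak set explains a count. Where the lower random limit was 0, a list with a median of 0 could hardly be called below. Kept calls in such runs say little, and some of the 16 were ties of list and random medians at 0. The location ratios (1.65 to 1.76 in gene bodies, 0.752 to 0.898 within 500 bp of an end, 2.16 to 2.43 at 1 to 2.5 kb, 0.378 to 0.482 beyond 25 kb), the profile (5.69 to 6.03) and the X ratio (0.0434 to 0.0973) kept their calls in each alternative run. Keeping the 50% of peaks with the higher q rank left 18176 peaks and placed housekeeping genes at percentile 47.3. The 25% of highest fold left 9215 peaks and placed activity-regulated genes at 49.985 and housekeeping genes at 49.9. With gene bodies alone activity-regulated genes stood at 48.9. In each of these runs the list's median and the median of its random lists were 0, so the percentiles reflect ties and not a measured loss. With 50 kb flanks the percentiles were 0.62 for inhibitory neuron, 0.89 for astrocyte, 0.19 for endothelial and pericyte, 1.12 for social neuropeptide and 0.1 for epithelial genes, and 85.6 for activity-regulated and 95.1 for housekeeping genes. By the mean, they were 0.03 for inhibitory neuron, 0.03 for social neuropeptide, 1.8 for endothelial and pericyte, 0.39 for hepatocyte, 0.25 for epithelial and 0.44 for Hox genes, and 85.6 for synapse, 93.2 for activity-regulated and 90.2 for housekeeping genes. In the same order, the mean without X genes gave 0.01, 0.05, 1.48, 0.45, 0.25 and 0.44, then 84.9, 92.5 and 91.85. The mean without high-background peaks gave 0.03, 0.03, 1.83, 0.39, 0.25 and 0.485, then 85.7, 94.0 and 90.5. The share of members with a peak gave 0.035, 1.79, 0.16, 1.32, 0.39 and 0.44 for the 6 lower lists and 96.3 for housekeeping genes, while synapse genes stood at 97.52 and activity-regulated genes at 100. Setting peaks within 2.5 kb against those beyond 25 kb turned the near minus far difference to 0.0291 in fold and 31 bp in width. Joining at 5 kb gave a top cluster of 26951 bp. Planned runs on start sites, promoters, CpG content and motifs were not run, since they need strand or sequence. No listed peak had fewer than 16 fragments, so a locus without a peak may still carry weaker enrichment.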

Other observations

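The families below and the 3 tests on the X were chosen after the data were examined, as was the choice of the 6 families taken as neuronal, while the wording of the test for neuronal families was written before their percentiles were seen. Genes grouped here as neuronal RNA-binding and splicing factors had more of their loci under H3K4me1 peaks than length-matched random lists. They stood at percentile 99.98 by median and 98.9 by mean, and 15 of 17 carried a peak. Whether these genes are particular to neurons was not examined. Celf2 had 61 peaks over 6.99% of its locus, Mbnl1 had 20 over 8.36% and Rbfox3, which encodes the neuronal marker NeuN, had 33 over 4.51%. Ankyrin and spectrin genes, which build the membrane skeleton of axons, carried peaks at 7 of 7 loci (99.75 by median, 99.5 by mean). Sptbn1 had 34 peaks over 15.6% of its locus, Ank2 had 39 over 4.76% and Ank3 had 23 over 4.24%. MAP kinase cascade genes stood at 99.3 by median and 96.7 by mean, with Mapk3 at 10.5% and Map4k4 at 9.56%. With the 50% of peaks of higher q rank these 3 families stood at 98.5, 99.8 and 99.6. Of 24 families, 5 lay above and 2 below by median, against 4 above and 4 below by mean, and some of these calls would arise by chance.

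Ribosomal protein genes (35 of 64 with a peak) and zinc finger genes (80 of 133) stood at percentiles 100 and 99.6 by median and 99.97 and 98.3 by mean. Their medians were at 50 and 49.995 when only the 50% of peaks with the higher q rank were kept. These values stand at or next to a tie with the random lists, so they do not tell whether the excess was lost. Ribosomal protein genes have many near-identical copies. Collagen genes lay below the random range by median (0.42) and by mean (0), with a peak at 12 of 35. Cadherin and protocadherin genes lay below it by median (1.92), where their median of 0 tied with the lower limit, and within it by mean (34.6). With the stronger 50% of peaks the medians of both lay within the range (17.6 for collagen, 24.1 for cadherin genes). There too a median of 0 could tie with random medians of 0. By mean alone, chemokine and interleukin genes (percentile 0, a peak at 12 of 67), Wnt and frizzled genes (0.13, 3 of 21) and keratin genes (0.2, 0 of 13) also lay below it.

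Length alone was weighed as an explanation for the coverage of brain gene families, since long genes gather more peaks. After matching on locus length, the splicing factor family, 1 of 6 taken as neuronal, stood at percentile 99.98. That is the value given above and not a further test, and it argues against length alone for that family. Ankyrin and spectrin genes (99.75) and MAP kinase cascade genes (99.3), not among the 6, also lay above the limits after matching. The other 5 of the 6, channel and receptor families, stood at 15.6 to 93.2, and the median of the 6 was 37.4. Both outcomes written for neuronal families were thus met. They did not exclude each other, so the test could not decide for the 6 as a set, and length stays open for those 5. Among those 5, only GABA-A receptor genes had a median above that of their random lists (1.98% against 0.872%). No biological explanation was tested.

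The scarcity of peaks on the X was weighed against 3 explanations. A smaller number of genes was argued against, since the X had 0.188 peaks per protein-coding gene and the lowest autosomal sequence 0.933. A raised background along the X stays open: 51.6% of X peaks lay at the lowest background, above the 29.4 to 40.5% on autosomal sequences, yet 29.0% had a background over 5 times the lowest, also above the autosomal 0 to 2.38%, and the test sees called peaks only. A candidate explanation is that 1 X copy lowers the ChIP pileup while the lowest background, shared by all sequences, stays where it is: cutting autosomal pileups to 1 copy predicted a median of 47.4 X peaks (18.2 to 105), and 62 were observed, or 44 against 41.3 (15.9 to 102) without high-background peaks. The test assumed the same enrichment on the X as on autosomes and compared counts only, not peak strength. Pileups cut to 1 copy should leave weaker peaks, yet 36 of the 62 X peaks were among those of higher q rank. For that set the ratio of the X to the autosomal median was 0.0711, against 0.0609 for all peaks. These values go against the 1-copy explanation, but they include X peaks of high background. The match in count therefore does not settle it. A biological difference between the X and autosomes stays open and untested.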
